A study of Caenorhabditis elegans with 24 samples.

How the data were processed

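RNA from whole worms was sequenced after polyA enrichment on a BGISeq500, per the labels, in 24 samples of 8 groups, 3 replicates each: N2 and VC3201 worms on control, cco-1, elt-2, or mixed cco-1 and elt-2 RNAi bacteria for 2.5 days at 20 °C. Only the deposited processed tables were used. Per the submitters' processing notes, STAR 2.73a, edgeR 3.24.3 and the genome build WBcel235 (ce11) were used, and the read counter and annotation release are not given in the sources used here. The expression values are CPM for 16927 genes, which the authors made by quantile-normalizing counts over the 24 libraries and then scaling each value plus 0.5 to a common total. This was tested on the table: the column sums were 1000373 in every library, and the sorted libraries agreed within 1% at 52.6% of ranks. The authors also deposited log2 fold changes, p-values with Benjamini-Hochberg adjusted p-values (Limma-Voom per the key sheet), and dependency scores, each a quotient of the authors' log2 fold changes. These deposited statistics were used only to describe the authors' lists of raised, ELT-2-dependent and ATFS-1-dependent genes, and for the change of hsp-60 with cco-1 RNAi in N2.

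Samples were grouped by strain and RNAi as the labels give them, and no library was left out. Genes with a mean of at least 1 CPM in at least 1 group were kept, 14561 in all. Values were transformed to log2(CPM + 1) and fitted in 1 linear model of group means over all 24 libraries (16 residual degrees of freedom) with limma 3.58.1 in R 4.3.3, using empirical Bayes with an intensity trend. Tests were 2-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The comparisons were each RNAi against control in either strain, both RNAi against cco-1 RNAi, VC3201 against N2 on control, and the interactions of cco-1 with elt-2 RNAi and of cco-1 RNAi with strain. A model of raw counts had been planned. Since the table holds normalized values, the limma procedure written for that case was used instead. The interaction of elt-2 RNAi with strain was added after the data were seen. Genes raised by cco-1 RNAi in N2 were intersected with genes lower with both RNAi, and with genes lower in VC3201 on cco-1 RNAi, and compared with 20 simulations without an effect and with effects dealt at random.

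There were 29 gene lists, on mitochondrial, lysosomal, stress, detoxification and tissue-marker genes. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone. Enrichment of the lists in the authors' dependent lists was tested with Fisher's exact test, 2-sided, against the authors' raised list. Gene positions came from the Ensembl annotation of WBcel235, which held 14487 of the tested genes. Named genes followed a rule: the targeted genes, the 10 raised and 10 lowered genes with the largest log2 fold change among called genes with a mean of at least 10 CPM and no overlap between the libraries compared (no overlap rule for interactions), and up to 4 members of each list described, those with the smallest p-values. The text names some of the genes that the rule gives. The groups, comparisons, lists, rule and all but 1 of the alternatives were chosen before the data were examined.

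Quantile normalization removes the library totals. Low values fall into ties that carry the order of the original counts, so reads were ranked back for 54.8 to 63.4% of genes per library, and for 8013 genes in every library, of which 5647 were tested and were also fitted from the reads themselves. A value of 1 CPM corresponded to 8 to 38 reads, and 10 CPM to 108 to 337 reads. Between replicates, the chi-square per gene of these reads was 1.24 to 1.61 over 24 pairs, near counting error. The rank order of very abundant genes fixes their values, so the SD of the top genes is not a measure of their error.

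Alternatives were pseudocounts of 0.5 and 5, no filter on low values, limma-voom, a minimum of 2-fold change, the replicate number as a block, fits of only the groups compared, leaving out each library, and a scale on which the quantile normalization was partly undone, which was chosen after seeing the data. On that scale, reads ranked back were used where available, and above them each library was rescaled by 1 factor, so that the shape of the distribution above the ranked range was not undone. Other splits of the samples were counted as tests of the groups, and interactions were also counted in 100 sets, the real one included, with additive group means and permuted residuals in the others. The pipeline was tested on simulated data with 200 changed genes: for cco-1 RNAi in N2, 70.1% of genes changed 1.5-fold, 86.6% changed 2-fold and 97% changed 4-fold were recovered, with 8 false calls, and for the interaction in N2 50.7%, 79.1% and 90.9%, with 4 false calls. A simulated list effect was found in 20 of 20 runs, with 0 other lists called.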

Results

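Whole Caenorhabditis elegans worms were profiled by polyA-enriched RNA sequencing in 24 libraries, 3 in each of 8 groups. Worms of N2, the wild-type strain, and of VC3201, a strain that the labels call an atfs-1 mutant, received control RNAi bacteria, cco-1 RNAi, elt-2 RNAi, or cco-1 and elt-2 RNAi mixed. cco-1 encodes a subunit of cytochrome c oxidase in the respiratory chain, elt-2 a GATA transcription factor of the intestine, and atfs-1 the transcription factor of the mitochondrial unfolded protein response. The worms were fed from hatching and collected 2.5 days later, at 20 °C, as late larvae or young adults. The labels give elt-2 RNAi as 50% of the bacteria, whereas the authors' key sheet gives 25%. The deposited values are CPM, read counts scaled to a common library total, which the authors had first quantile-normalized across the libraries. Library totals from before that step are not in the files used here. Reads recovered from tied low values gave a mean of 13.3, 18.7, 21.7 and 24 reads at 1 CPM in N2 on control, cco-1, elt-2 and mixed RNAi, and 9.33, 18, 35 and 38 in VC3201. Values below are means ± SD in CPM over 3 libraries, and changes are log2 fold changes of CPM + 1, a scale that understates changes of genes near 1 CPM. Differences were tested with limma over 14561 genes, with Benjamini-Hochberg adjusted p-values. The labels do not say whether replicates were separate cultures, so each p-value measures the spread between these samples.

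The targeted genes were examined first, to learn how far each RNAi and the mutant strain lowered its transcript. Levels of cco-1 (WBGene00000371, chromosome I, 9788725 to 9790050 in WBcel235) fell from 292 ± 35.5 CPM on control bacteria to 128 ± 5.85 CPM with cco-1 RNAi in N2, a change of -1.18 (adjusted p = 4.87e-13). In VC3201 they fell from 346 ± 11.1 to 125 ± 11.3 CPM (-1.47, adjusted p = 1.04e-15), with a strain difference of -0.28 (adjusted p = 0.0373) that was lost when any 1 of 6 libraries was left out (adjusted p = 0.0049 to 0.128 over all alternatives). Adding elt-2 RNAi to cco-1 RNAi lowered cco-1 further, to 72.9 ± 5.99 CPM in N2 (-0.80, adjusted p = 7.96e-10) and 67.4 ± 3.61 CPM in VC3201 (-0.88, adjusted p = 2.08e-11). Transcripts of elt-2 (WBGene00001250, chromosome X, 10481240 to 10483441) fell with elt-2 RNAi from 17.3 ± 1.70 to 10.5 ± 0.958 CPM in N2 (-0.68, adjusted p = 0.00845) and from 16.9 ± 0.673 to 10.4 ± 4.93 CPM in VC3201 (-0.73, adjusted p = 0.00196). In VC3201 the elt-2 RNAi libraries stood at 6.52, 8.84 and 16 CPM in order of replicate, so elt-2 was hardly lowered in replicate 3. The change was -1.06 without replicate 3 and -0.47 without replicate 1. Protease genes that elt-2 RNAi lowered were low in replicate 3 as well. In order of replicate, cpr-5 stood at 0.33, 0.494 and 0.31 CPM, asp-2 at 0.303, 0.38 and 0.364, and cpr-6 at 0.15, 0.125 and 0.189. The elt-2 level of replicate 3 therefore does not show that RNAi failed in it. Under cco-1 RNAi alone, elt-2 stood at 13.8 ± 1.21 CPM in N2 and 18.9 ± 2.14 CPM in VC3201, and neither difference from control passed the threshold (adjusted p = 0.28 and 0.557). In N2 it passed when only these groups were fitted (adjusted p = 0.0264, the lowest of the alternatives, which ranged up to 0.505). Levels of atfs-1 (WBGene00013878, chromosome V, 14193663 to 14197700) were 74.5 ± 3.47 CPM in N2 and 21.3 ± 1.31 CPM in VC3201 on control bacteria (-1.76, adjusted p = 9.09e-19). They rose with cco-1 RNAi to 83.6 ± 2.34 CPM in N2 (0.17, adjusted p = 0.0421) and to 26.2 ± 2.77 CPM in VC3201 (0.28, adjusted p = 0.00032). The call in N2 was lost with the quantile normalization partly undone (adjusted p = 0.0777), an alternative chosen after seeing the data, and when any 1 of 4 libraries was left out (adjusted p = 0.0193 to 0.164 over all alternatives).

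**Figure D1:**
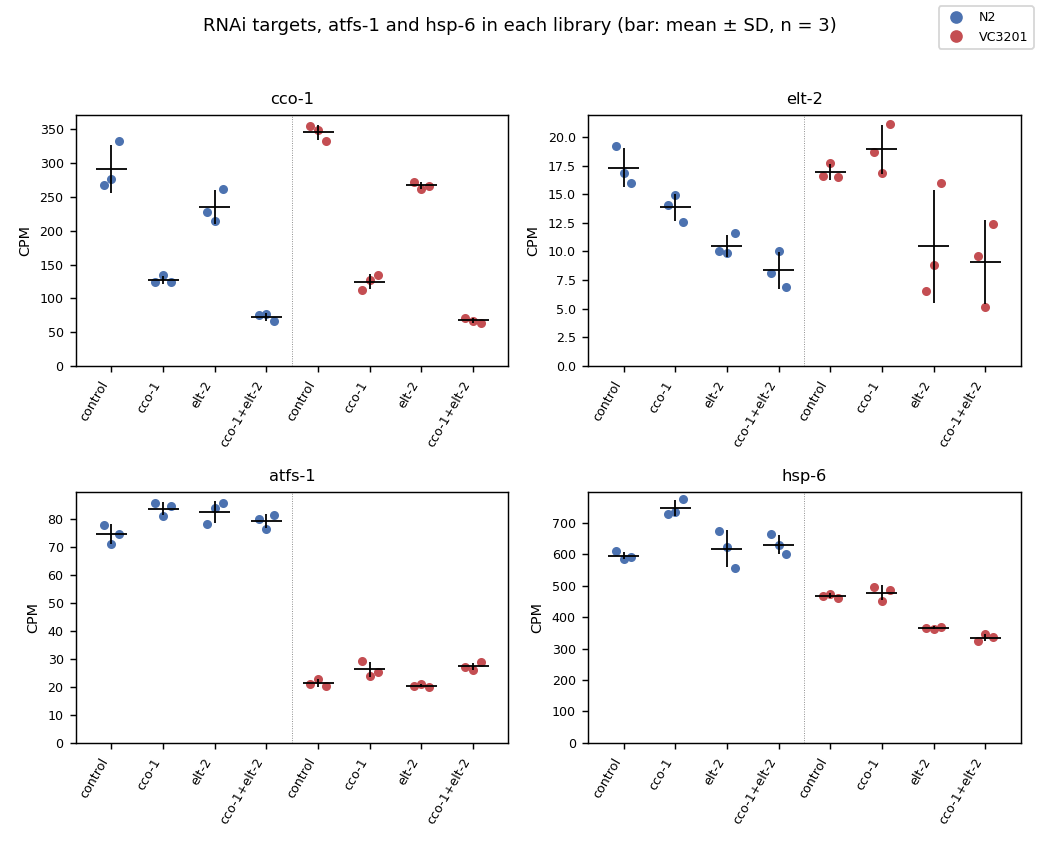
CPM of cco-1, elt-2, atfs-1 and hsp-6 in each of the 24 libraries by group; points are libraries and bars are group means ± SD (n = 3). The cco-1 libraries with both RNAi lie lowest in either strain, and atfs-1 is lower in every VC3201 group than in any N2 group.

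The comparison of cco-1 RNAi with control in N2 asks which transcripts respond to a block in the respiratory chain. An aspartyl protease gene, asp-8 (WBGene00019105, chromosome V, 3024549 to 3027931), rose from 7.45 ± 1.1 to 105 ± 1.82 CPM (3.65, adjusted p = 1.6e-21). The acyl-CoA synthetase gene acs-2 (WBGene00009221) rose from 8.11 ± 1.94 to 78.1 ± 3.28 CPM (3.14), the C-type lectin gene clec-4 (WBGene00012583) from 6.37 ± 1.57 to 60.7 ± 3.14 CPM (3.09), and the detoxification gene ugt-62 (WBGene00010904) from 70.8 ± 1.52 to 416 ± 3.23 CPM (2.54, adjusted p = 7.79e-24). Among lowered genes, the fatty acid desaturase genes fat-7 (WBGene00001399) and fat-5 (WBGene00001397) fell from 68.6 ± 1.1 to 4.26 ± 0.580 CPM (-3.73) and from 54.2 ± 2.48 to 7.63 ± 0.236 CPM (-2.68). The yolk protein gene vit-4 (WBGene00006928) fell from 5171 ± 157 to 347 ± 28.9 CPM (-3.90), and the cathepsin B gene cpr-4 (WBGene00000784) from 223 ± 11 to 35.7 ± 0.651 CPM (-2.61). In all, 2541 genes rose and 2385 fell, and 346 of these changed at least 2-fold. The libraries of both groups did not overlap for 6346 genes, where chance gives 10% of genes.

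Of 18 mitochondrial chaperones, proteases and import factors, the effectors of the mitochondrial unfolded protein response, 13 rose, 1 fell and 4 did not pass the test, and adjusted over the list alone the counts were also 13 and 1. Their median change was 0.25 (adjusted p = 9.34e-06). The import channel gene timm-23 (WBGene00008857) rose from 61.4 ± 2.59 to 98.9 ± 4.16 CPM (0.68) and the chaperone gene dnj-10 (WBGene00001028) from 51.7 ± 4.43 to 73.1 ± 1.77 CPM (0.49). The mitochondrial Hsp70 gene hsp-6 (WBGene00002010), chosen after its values were seen, stood at 747 ± 25.9 CPM against 596 ± 12 CPM on control. Another chaperone gene of this list, hsp-60, did not rise, with a log2 fold change of -0.19 in the authors' deposited statistics. Of 44 lysosomal hydrolase genes, 9 rose and 21 fell (10 and 21 adjusted over the list alone), with a median of -0.19 (adjusted p = 0.0013). The aspartyl protease gene asp-10 (WBGene00007605) rose from 78.2 ± 5.50 to 412 ± 23.2 CPM (2.38), while the cathepsin Z gene cpz-1 (WBGene00000788) fell from 448 ± 31.8 to 113 ± 3.59 CPM (-1.98). Of 22 subunits of the V-ATPase, the proton pump that acidifies lysosomes, 14 rose and 0 fell (15 and 0 adjusted over the list alone; median 0.2, adjusted p = 0.00016). That list lost its call with adjusted p = 0.128 with an estimated correlation. The intestinal subunit gene vha-6 (WBGene00006915) rose from 221 ± 7.91 to 418 ± 11.5 CPM (0.92). Of 19 spermatogenesis markers 13 rose and none fell (median 0.53, adjusted p = 4.77e-06), and of 6 yolk protein genes 4 fell (median -2.60, adjusted p = 6.86e-08). The yolk protein gene vit-2 was the most abundant transcript in both groups, and its value there was fixed by the normalization, so a change could not be measured. Of 29 lists 13 passed the threshold, and 5 of them held with an estimated correlation.

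Control and elt-2 RNAi were compared in N2 to find transcripts that need ELT-2 in worms without the respiratory block. Several lysosomal protease transcripts fell strongly. The aspartyl protease gene asp-2 (WBGene00000215) fell from 534 ± 24.8 to 4.46 ± 0.645 CPM (-6.62, adjusted p = 4.65e-32), and the cathepsin B genes cpr-6 (WBGene00000786) and cpr-5 (WBGene00000785, chromosome V, 1132598 to 1134036) from 721 ± 25.1 to 5.42 ± 1.68 CPM (-6.85) and from 368 ± 8.66 to 4.56 ± 0.667 CPM (-6.06). The lysozyme gene ilys-5 (WBGene00017691) fell from 324 ± 30.5 to 4.26 ± 1.17 CPM (-5.97). Another cathepsin B gene, cpr-3 (WBGene00000783), rose instead, from 6.66 ± 0.751 to 243 ± 11.6 CPM (5.0, adjusted p = 1.95e-30). The noncoding RNA tts-1 (WBGene00006650) rose from 7.75 ± 1.27 to 224 ± 26 CPM (4.69). Raised genes numbered 3812 and lowered genes 3177, of which 1193 changed at least 2-fold, and 7777 genes had no overlap between groups, against 10% by chance.

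All 17 members of the intracellular pathogen response, a program that worms mount against microsporidia and viruses, rose with elt-2 RNAi (also 17 adjusted over the list alone; median 2.91, adjusted p = 9.22e-20). One of them, eol-1 (WBGene00045401, chromosome V, 13979462 to 13980907), rose from 1.17 ± 0.194 to 59.0 ± 4.44 CPM (4.79). Of 44 lysosomal hydrolase genes 23 fell and 12 rose (24 and 13 adjusted over the list alone; median -0.33, adjusted p = 3.17e-05). Of 56 UDP-glucuronosyltransferases, which conjugate foreign compounds, 33 fell and 10 rose (median -0.60, adjusted p = 6.88e-08); ugt-22 (WBGene00007455) fell from 83.0 ± 2.98 to 2.81 ± 0.615 CPM (-4.47). Of 18 intestine markers 14 fell (median -0.62, adjusted p = 3.17e-05), among them vha-6, from 221 ± 7.91 to 61.3 ± 4.08 CPM (-1.84). Another intestine marker, lec-8 (WBGene00002271), rose from 379 ± 21.3 to 1049 ± 109 CPM (1.46). Autophagy genes rose in 20 of 28 cases and fell in 2 (median 0.25, adjusted p = 0.000145), with the receptor gene sqst-1 (WBGene00011737) going from 80.1 ± 1.48 to 243 ± 5.48 CPM (1.59) and the Atg8 gene lgg-1 (WBGene00002980) from 204 ± 4.29 to 416 ± 27.6 CPM (1.02). Among the 18 mitochondrial stress effectors 11 fell and 1 rose (median -0.19, adjusted p = 0.00244), but adjusted p = 0.0768 with an estimated correlation. The chaperonin gene hsp-60 (WBGene00002025) fell from 226 ± 10.2 to 114 ± 14.1 CPM (-0.98). Of 29 lists 20 passed, and 11 held with an estimated correlation.

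**Figure D2:**
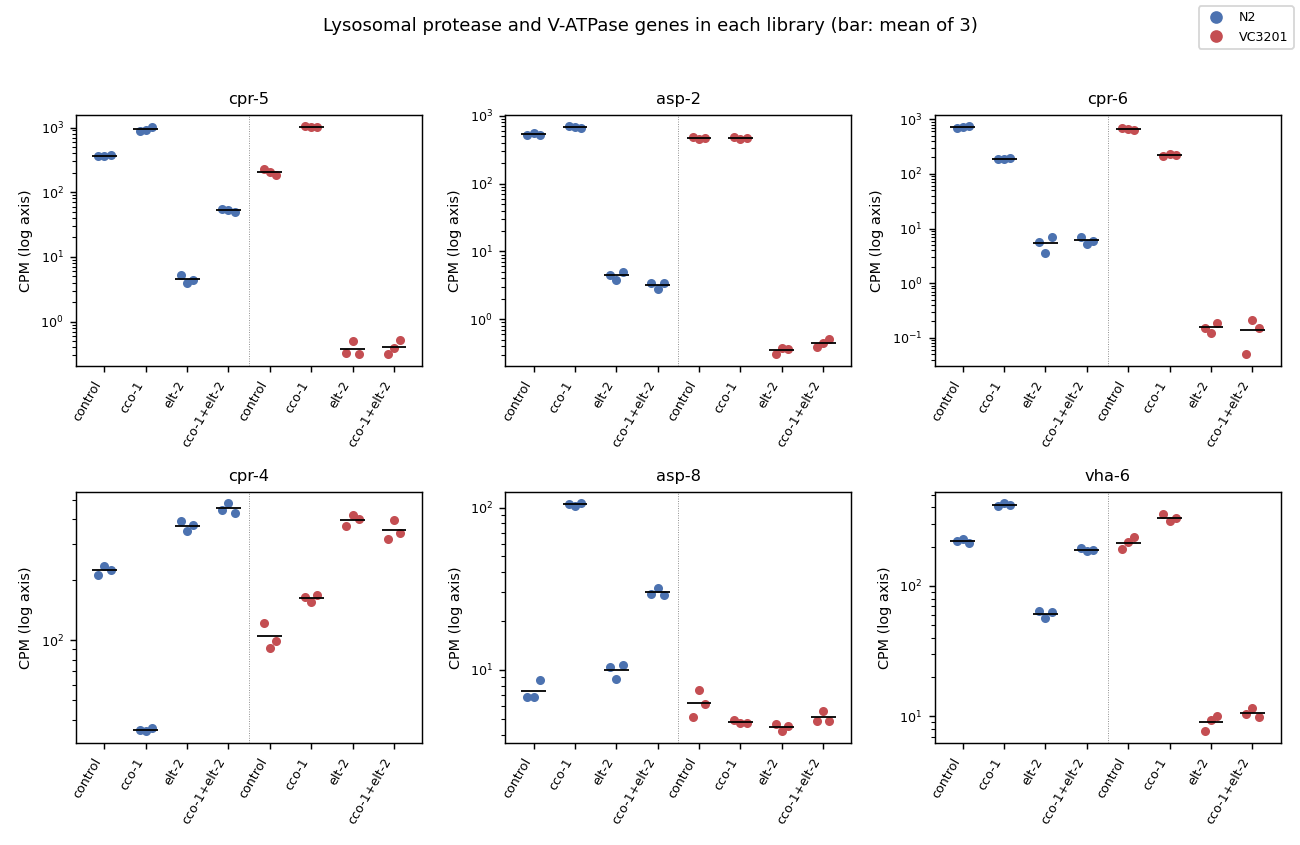
CPM of 6 lysosomal genes, on a log axis, in each of the 24 libraries by group; points are libraries and bars are group means. asp-2, cpr-5 and cpr-6 are lowest in the groups with elt-2 RNAi, and asp-8 is highest in N2 with cco-1 RNAi.

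Whether the response to cco-1 RNAi needs elt-2 was examined by comparing N2 worms on both RNAi with those on cco-1 RNAi. Several lysosomal protease transcripts were again reduced. asp-2 fell from 683 ± 15.6 to 3.21 ± 0.374 CPM (-7.35, adjusted p = 2.63e-33), cpr-6 from 190.1 ± 3.96 to 6.09 ± 0.948 CPM (-4.76), and cpr-5 from 939 ± 61.8 to 52.6 ± 3.38 CPM (-4.13). ugt-62 fell from 416 ± 3.23 to 59.8 ± 1.66 CPM (-2.78), and vha-6 from 418 ± 11.5 to 189 ± 5.30 CPM (-1.14). eol-1 rose from 1.23 ± 0.137 to 60.2 ± 3.29 CPM (4.78). The counts were 2563 raised and 2401 lowered genes, with 805 changed at least 2-fold and 6963 without overlap between groups, where 10% would not overlap by chance.

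Of the mitochondrial stress effectors 15 of 18 fell and none rose (16 lowered adjusted over the list alone; median -0.39, adjusted p = 1.3e-08). hsp-60 fell from 198 ± 7.54 to 125 ± 2.65 CPM (-0.66), dnj-10 from 73.1 ± 1.77 to 46.3 ± 0.249 CPM (-0.65), and mppa-1 (WBGene00022159), a subunit of the protease that trims imported proteins, from 38.1 ± 1.56 to 20.6 ± 0.692 CPM (-0.86). However, cco-1 RNAi had not raised hsp-60, and elt-2 RNAi alone changed it by -0.98 in N2. The fall of hsp-60 therefore does not show that a response to cco-1 RNAi needs elt-2. Genes of the mitochondrial ribosome fell in 49 of 66 cases (median -0.26, adjusted p = 1.74e-10). All 11 respiratory chain subunits encoded in mitochondrial DNA fell (median -0.76, adjusted p = 5.93e-06), although adjusted p = 0.106 with an estimated correlation. Among lysosomal hydrolases 19 fell and 13 rose (19 and 14 adjusted over the list alone; median -0.1, mean -0.73, adjusted p = 0.00149). V-ATPase subunits rose in 11 cases and fell in 1 (median 0.18, adjusted p = 0.0153), but adjusted p = 0.246 with an estimated correlation and 0.0688 with the normalization partly undone (0.0163 with a replicate block). All 17 intracellular pathogen response genes rose (median 2.54, adjusted p = 1.34e-24). Here 20 of 29 lists passed and 14 held with an estimated correlation.

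The interaction in N2 asks whether cco-1 RNAi acted differently once elt-2 RNAi was present. acs-2 rose with cco-1 RNAi on its own, whereas with elt-2 RNAi it stood at 58.6 ± 3.67 CPM without and 59.7 ± 1.30 CPM with cco-1 RNAi (interaction -3.11, adjusted p = 9e-15). The alcohol dehydrogenase gene sodh-1 (WBGene00010790) went from 19.8 ± 2.01 to 70.8 ± 4.68 CPM with cco-1 RNAi, but from 314 ± 33.6 to 143 ± 4.37 CPM on elt-2 RNAi (interaction -2.91). asp-8 increased less on elt-2 RNAi, from 9.99 ± 1.06 to 30.1 ± 1.81 CPM (interaction -2.15, adjusted p = 4.21e-12). In the opposite direction, cpr-4 fell with cco-1 RNAi on control bacteria and stood at 372 ± 19.9 and 454 ± 25.1 CPM on elt-2 RNAi without and with cco-1 RNAi (interaction 2.89, adjusted p = 7.36e-17). hsp-6 had an interaction of -0.29 (adjusted p = 0.0101), from 618 ± 59.2 to 631 ± 30.9 CPM on elt-2 RNAi. The interaction was positive for 1032 genes and negative for 867. Of the mitochondrial stress effectors 7 of 18 had a negative interaction (9 adjusted over the list alone; median -0.17, adjusted p = 0.00753, but adjusted p = 0.199 with an estimated correlation). Lysosomal hydrolases had 18 positive and 9 negative interactions (median 0.14, adjusted p = 0.0119), and adjusted p = 0.105 with an estimated correlation. None of the 13 lists past the threshold held with an estimated correlation.

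Of the 2541 genes raised by cco-1 RNAi in N2, 556 were lower with both RNAi than with cco-1 RNAi, and 218 of these also had a negative interaction. That is 21.9% of the raised genes, while 2401 of all 14561 tested genes were lower in that contrast. Both contrasts share the N2 libraries with cco-1 RNAi. In 20 simulated data sets in which elt-2 RNAi had no effect, limma counted 0 such genes in each, and at an unadjusted p a mean of 128.1, against 617 observed. With no gene changed in that contrast, the adjustment leaves almost no calls by construction, so the count of 0 decides nothing. When the measured elt-2 effects were dealt at random among the raised genes of like level, the mean count was 705. This gives no expectation over all genes. The simulations add spread to measured means, and those without an effect called a mean of 2969.6 genes raised. The counts of 705 and 556 are therefore not directly comparable. Of the 556 genes 292 were also lowered by elt-2 RNAi alone. After elt-2 RNAi, 840 of the raised genes were still raised by cco-1 RNAi.

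VC3201 and N2 were compared on control bacteria to learn what the strain changes before any RNAi. Cuticle genes showed low levels in VC3201. The collagen genes sqt-1 (WBGene00005016) and dpy-13 (WBGene00001074) were at 2.43 ± 0.699 CPM against 18.7 ± 8.65 CPM in N2 (-2.44) and at 5.05 ± 1.16 against 34.3 ± 14 CPM (-2.48), and the molting protein gene mlt-11 (WBGene00012186) at 7.37 ± 0.864 against 50.6 ± 3.93 CPM (-2.63). Of 19 hypodermis and cuticle markers 17 were lower (median -1.40, adjusted p = 1.54e-10). hsp-6 was lower, at 468 ± 7.75 CPM (-0.35, adjusted p = 6.25e-06), while the import receptor gene tomm-20 (WBGene00009092) was higher, at 78.9 ± 1.97 against 32.5 ± 4.33 CPM (1.26). Among the mitochondrial stress effectors 5 were higher and 3 lower (median 0.05, adjusted p = 0.408). Of 17 genes of the endoplasmic reticulum stress response 14 were lower (median -0.52, adjusted p = 1.54e-10), for example the disulfide isomerase gene pdi-2 (WBGene00003963), at 913 ± 30.4 against 1498 ± 69.9 CPM (-0.71). Mitochondrial ribosome genes were higher in 49 of 66 cases (median 0.23, adjusted p = 2.38e-08), and autophagy genes lower in 16 of 28 (median -0.22, adjusted p = 0.000496). Proteasome genes were higher in 28 of 32 cases (median 0.25, adjusted p = 1.29e-07), but adjusted p = 0.107 with an estimated correlation. In all 3895 genes were higher and 3284 lower in VC3201, 549 of them at least 2-fold, and 7772 genes did not overlap between strains (10% by chance). Of 29 lists 13 passed and 4 held with an estimated correlation.

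In VC3201, cco-1 RNAi was compared with control to see the response when atfs-1 is mutated. The collagen gene col-39 (WBGene00000616) rose from 21.2 ± 0.365 to 393 ± 41.1 CPM (4.15) and the small heat shock gene hsp-16.41 (WBGene00002018) from 7.16 ± 0.700 to 111 ± 8.55 CPM (3.78). cpr-5 rose from 205 ± 21 to 1019 ± 23.7 CPM (2.31) and sqst-1 from 51.7 ± 4.28 to 333 ± 32.8 CPM (2.66). The yolk protein gene vit-3 (WBGene00006927, chromosome X, 3567355 to 3572549) fell from 5446 ± 319.8 to 131 ± 3.21 CPM (-5.36), and fat-7 from 50.6 ± 4.30 to 2.95 ± 0.601 CPM (-3.72). The totals were 3921 raised and 5397 lowered genes, 1200 of them changed at least 2-fold, with 9256 not overlapping (10% by chance). Of the mitochondrial stress effectors 9 fell and 1 rose (median -0.11, adjusted p = 0.0946), and with the normalization partly undone 12 fell (adjusted p = 0.0141, against 0.352 with an estimated correlation and 0.0883 with a replicate block). hsp-60 fell from 230.0 ± 6.87 to 151 ± 5.81 CPM (-0.60) and mppa-1 from 38.1 ± 1.64 to 22.9 ± 0.889 CPM (-0.71). Lysosomal hydrolases rose in 15 and fell in 16 cases (median 0.05, mean -0.02, with a test that pointed up; adjusted p = 0.742), and V-ATPase subunits rose in 17 of 22 cases (median 0.26, adjusted p = 0.000166). Stage and tissue markers moved with them. Cuticle markers rose in 15 of 19 cases (median 2.29, adjusted p = 2.15e-07), and all 20 oogenesis and early embryo markers fell (median -0.40, adjusted p = 9.09e-07). None of the 12 lists past the threshold held with an estimated correlation, the V-ATPase with adjusted p = 0.125 and the cuticle and oogenesis markers with adjusted p = 0.0832 and 0.0832.

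The interaction of cco-1 RNAi with strain tests whether the response depends on the atfs-1 mutant background. asp-8 stood at 6.26 ± 1.21 and 4.78 ± 0.123 CPM in VC3201 without and with cco-1 RNAi, unlike its rise in N2 (interaction -3.97, adjusted p = 1.92e-18). clec-4 was at 7.52 ± 0.577 and 2.41 ± 0.329 CPM there (interaction -4.41), and ugt-62 at 23 ± 0.120 and 31.4 ± 1.64 CPM (interaction -2.1). cpr-4, lowered in N2, went from 104.3 ± 16 to 162 ± 7.16 CPM in VC3201 (interaction 3.25, adjusted p = 6.55e-19). Of the mitochondrial stress effectors 16 of 18 had a negative interaction (17 adjusted over the list alone; median -0.34, adjusted p = 5.65e-07), with mppa-1 at -1.03. Mitochondrial ribosome genes had 46 negative interactions of 66 (median -0.33, adjusted p = 1.09e-08). Lysosomal hydrolases had 17 positive and 6 negative interactions (median 0.19, adjusted p = 0.00133), and heat shock genes 8 of 11 positive ones (median 0.84, adjusted p = 0.000134). Alongside, cuticle markers had 15 positive interactions (median 1.81) and oogenesis markers 19 negative ones (median -0.45). These 6 lists held with an estimated correlation, of 12 that passed. Over all genes, 2448 interactions were positive and 3371 negative. Of 13 molting genes, a list added after the data were seen, 9 had a positive interaction and 0 a negative one (median 0.7). On control bacteria they were lower in VC3201, by a median of -1.33. For major sperm protein genes, also added, the median interaction was 0.03. A difference in developmental stage between the groups therefore cannot be told apart here from dependence on atfs-1.

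Of the 2541 raised genes, 603 were lower in VC3201 than in N2 with cco-1 RNAi, and 421 of these also had a negative interaction with strain. Simulated data without a strain effect gave 0 such genes by limma, again by construction, and at an unadjusted p a mean of 132.7 against 634 observed. Effects dealt at random among the raised genes gave a mean of 757.9, with the same limits as for elt-2 RNAi. The ELT-2-related and strain-related sets shared 268 genes, against 131.9 expected if membership were independent and a mean of 205.8, at most 226, with effects dealt at random. In both strains cco-1 RNAi raised 1678 genes, against 684.2 expected if independent, and lowered 1617, against 884.0. Across genes, which are not independent replicates, the responses of both strains correlated with a Pearson's r of 0.584 and a Spearman's rho of 0.565.

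Of the genes that the authors' deposited table lists as raised by cco-1 RNAi, it gives 517 as ELT-2-dependent and 719 as ATFS-1-dependent. These lists were chosen on the same samples, so their direction here is not independent evidence. Of their tested raised genes, 1676 of 1708 were also called raised. Of 470 tested ELT-2-dependent genes, 360 were lower with both RNAi and 197 had a negative interaction. Of 658 tested ATFS-1-dependent genes, 320 had a negative interaction with strain. Within the authors' raised list, Fisher's exact test gave 11 fixed lists with an unequal share among ELT-2-dependent genes. All 7 mitochondrial stress effectors in the raised list were ELT-2-dependent (adjusted p = 0.00142), as were 6 of 9 lysosomal hydrolases (adjusted p = 0.039) and 6 of 8 intestine markers (adjusted p = 0.02), but 0 of 12 spermatogenesis markers (adjusted p = 0.039). Among ATFS-1-dependent genes 3 lists passed, with all 7 mitochondrial stress effectors (adjusted p = 0.00964), all 7 respiratory chain subunits encoded in mitochondrial DNA (adjusted p = 0.00964) and 13 of 15 cytochrome P450 genes (adjusted p = 0.00474). The authors' quotient was at most -0.252 in the ELT-2-dependent list and at most 0.749 in the ATFS-1-dependent list. With a quotient, a gene that rose little with cco-1 RNAi can enter on a small difference. Of the 517 ELT-2-dependent genes, 147 had an authors' adjusted p of 0.05 or more for elt-2 RNAi within cco-1 RNAi. The shares above therefore depend on that definition.

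With elt-2 RNAi in VC3201, compared with control there, several yolk and lysosomal transcripts fell strongly. vit-3 fell from 5446 ± 319.8 to 2.68 ± 0.566 CPM (-10.54) and vit-4 from 2864 ± 216 to 0.967 ± 0.219 CPM (-10.51). cpr-6 fell from 662 ± 39.4 to 0.155 ± 0.0323 CPM (-9.16), asp-2 from 469.9 ± 18.7 to 0.349 ± 0.0406 CPM (-8.45), and vha-6 from 215 ± 23.1 to 9.01 ± 1.22 CPM (-4.43). cpr-3 rose from 6.67 ± 0.562 to 868 ± 8.21 CPM (6.83), tts-1 from 3.1 ± 0.865 to 547 ± 40.6 CPM (7.08), and sqst-1 from 51.7 ± 4.28 to 742 ± 26.4 CPM (3.82). All 17 intracellular pathogen response genes rose (median 3.44, adjusted p = 6.4e-10). Of the lysosomal hydrolases 29 fell and 14 rose (median -0.71, adjusted p = 0.0135), and of the mitochondrial stress effectors 16 fell (median -0.66, adjusted p = 0.0027), hsp-60 from 230.0 ± 6.87 to 45.8 ± 3.75 CPM (-2.3). Developmental markers moved too. All 19 spermatogenesis markers rose (median 1.57, adjusted p = 2.45e-07), 18 of 19 cuticle markers rose (median 2.37, adjusted p = 1.71e-06), and 18 of 20 oogenesis markers fell (median -0.97, adjusted p = 2.74e-05). Only the pathogen response and spermatogenesis lists held with an estimated correlation, of 17 that passed. For lysosomal hydrolases adjusted p = 0.0689, for stress effectors adjusted p = 0.082, and for cuticle and oogenesis markers adjusted p = 0.0689 and 0.0762 with an estimated correlation. Counts were 5299 raised and 7195 lowered genes, 5144 changed at least 2-fold and 12611 not overlapping (10% by chance). The median over all genes was -0.18, and -0.03 after the quantile normalization was partly undone.

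**Figure D3:**
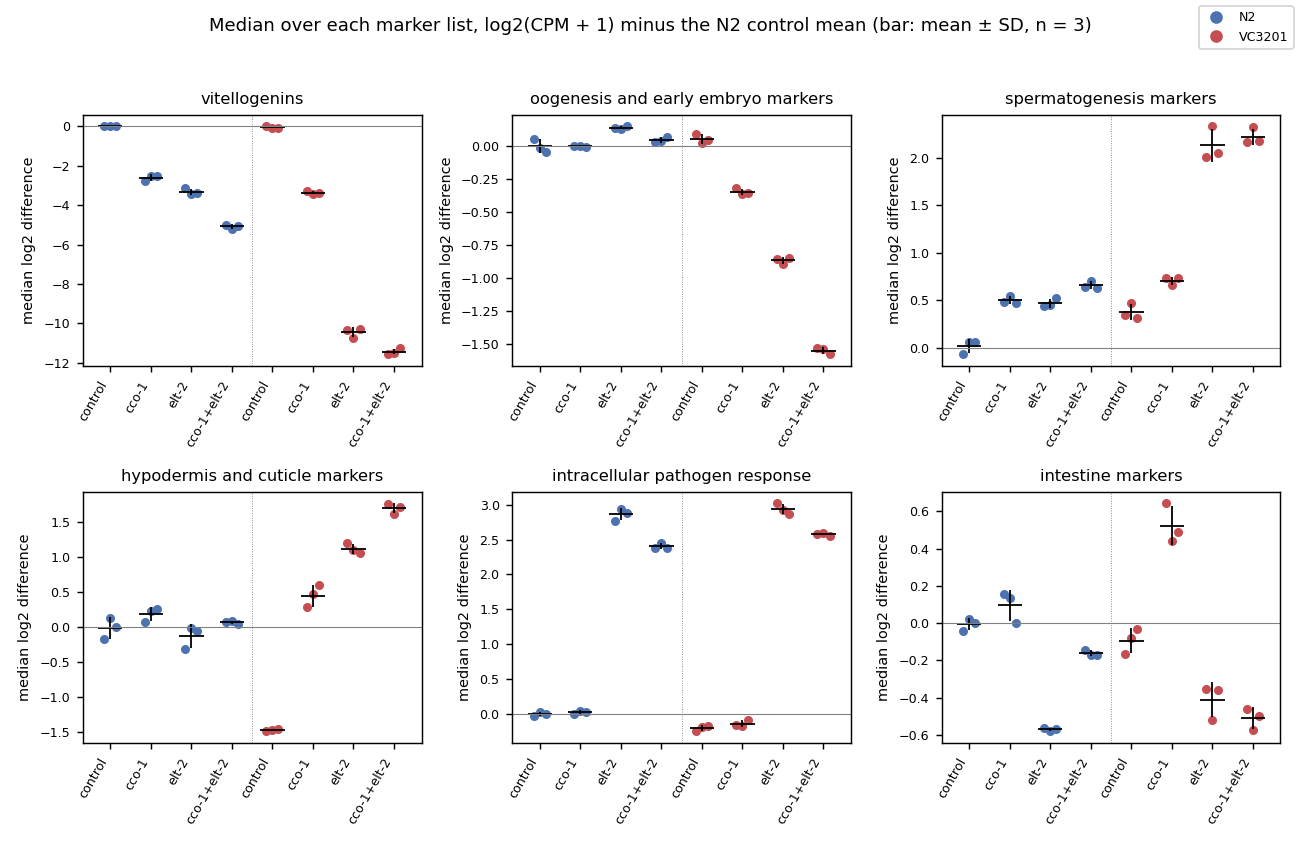
Median log2 level of 6 marker lists in each of the 24 libraries, relative to the N2 control mean, by group; points are libraries, and bars are group means ± SD (n = 3). Yolk protein genes and oogenesis markers are lowest, and cuticle and spermatogenesis markers highest, in the VC3201 groups with elt-2 RNAi.

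Adding elt-2 RNAi to cco-1 RNAi in VC3201 tests the need for elt-2 in the mutant. cpr-5 fell from 1019 ± 23.7 to 0.406 ± 0.101 CPM (-9.50, adjusted p = 2.04e-35), and the acyl-CoA dehydrogenase gene acdh-1 (WBGene00016943) from 470.5 ± 4.92 to 3.22 ± 0.201 CPM (-6.81). hsp-16.41 fell from 111 ± 8.55 to 0.693 ± 0.0955 CPM (-6.05), with all 11 heat shock genes lowered (median -0.74, adjusted p = 0.000451). Of the mitochondrial stress effectors 17 of 18 fell (median -0.52, adjusted p = 0.000873), but adjusted p = 0.0536 with an estimated correlation. Lysosomal hydrolases fell in 25 and rose in 14 cases (median -0.52, adjusted p = 0.00593), and pathogen response genes rose in all 17 cases (median 2.06, adjusted p = 3.32e-09). Oogenesis markers fell in 19 of 20 cases (median -1.23), and spermatogenesis markers rose in all 19 (median 1.25). Raised genes numbered 5316 and lowered genes 6491, with 3852 changed at least 2-fold and 12020 not overlapping (10% by chance), and 11 of 19 lists held with an estimated correlation. The effect of elt-2 RNAi within cco-1 RNAi correlated between strains, across genes, with a Pearson's r of 0.704 and a Spearman's rho of 0.63.

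The interaction in VC3201 asks whether cco-1 RNAi acted differently on elt-2 RNAi in the mutant. hsp-16.41 rose with cco-1 RNAi alone but stood at 0.691 ± 0.128 and 0.693 ± 0.0955 CPM on elt-2 RNAi without and with cco-1 RNAi (interaction -3.78). col-39 went from 241 ± 9.11 to 333 ± 17.4 CPM on elt-2 RNAi (interaction -3.68), and sqst-1 from 742 ± 26.4 to 928 ± 33.1 CPM (interaction -2.34). Heat shock genes had 8 negative interactions of 11 (median -0.94, adjusted p = 6.37e-06) and pathogen response genes 16 of 17 (median -0.91, adjusted p = 8.5e-09). These were the 2 of 14 lists that held with an estimated correlation. Cuticle markers had 13 negative interactions (median -1.53, adjusted p = 1.69e-05, but adjusted p = 0.137 with an estimated correlation). Interactions were positive for 3056 genes and negative for 2930, or 51.1% positive. With the quantile normalization partly undone the numbers were 2397 and 3684, or 39.4% positive.

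**Figure D4:**
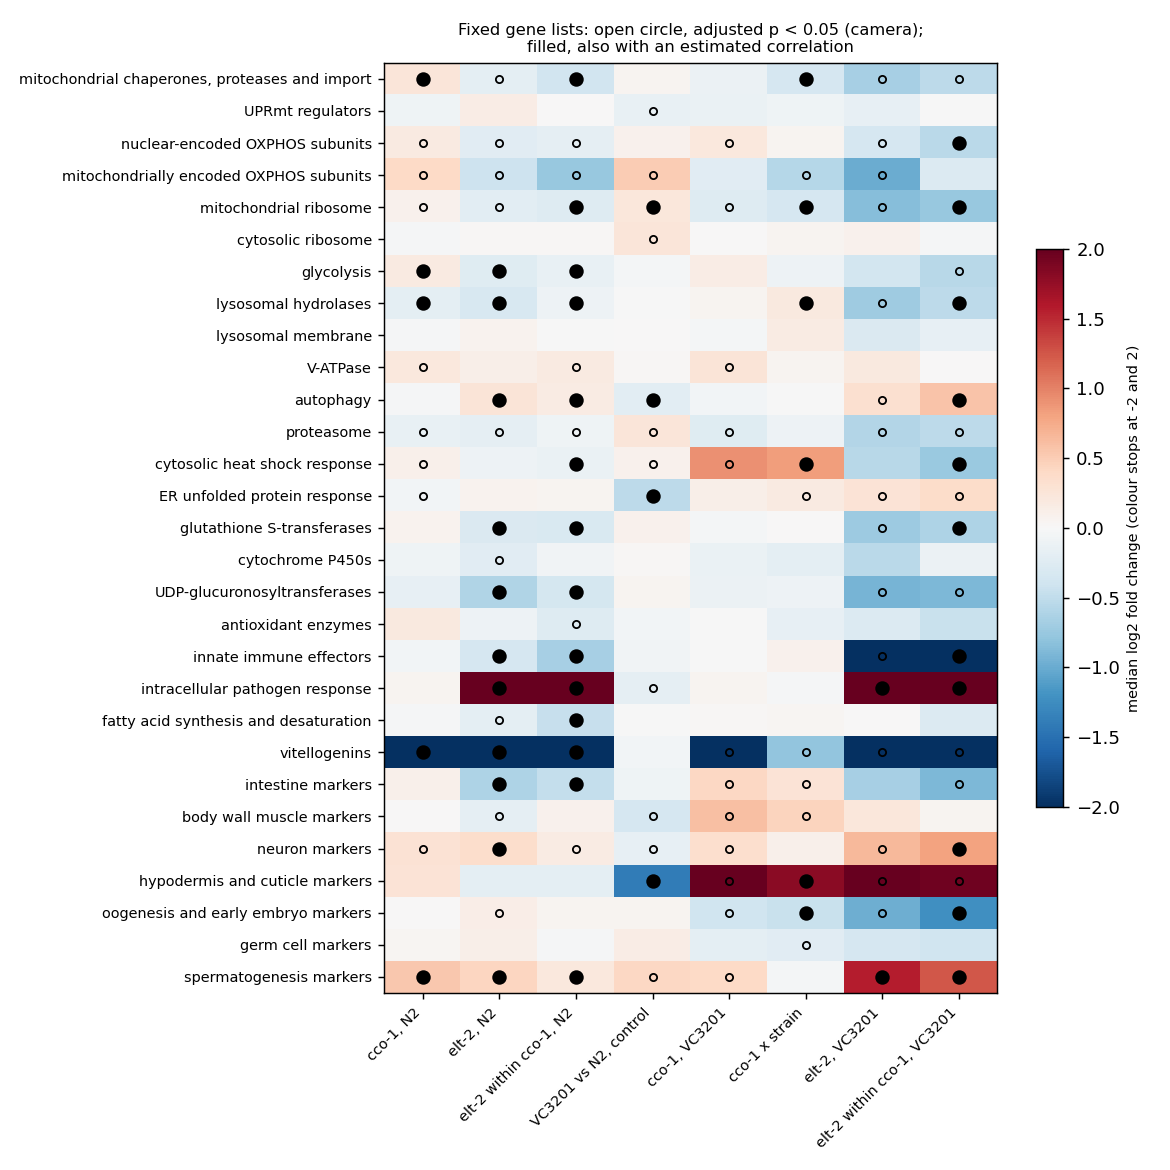
Median log2 fold change of the fixed gene lists in 8 comparisons; open circles mark adjusted p under 0.05 with the preset correlation, and filled circles lists that also held with an estimated correlation. The intracellular pathogen response is filled in each of the 4 comparisons of elt-2 RNAi, and the mitochondrial stress effectors in N2 for cco-1 RNAi and for elt-2 RNAi added to it, and for the interaction of cco-1 RNAi with strain.

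How many low genes rose or fell depended on the normalization. Among 5647 genes whose reads were recovered in every library, the share of raised genes among those called with cco-1 RNAi in N2 was 40.1% from the deposited values and 52.8% from the recovered reads. With elt-2 RNAi it was 44.9% and 61.3% in N2, and 46% and 62% in VC3201. With cco-1 RNAi in VC3201 it was 39.6% and 60.1%, and between the strains on control bacteria 55.2% and 36.9%. With elt-2 RNAi added to cco-1 RNAi it was 40.8% and 56.9% in N2, and 51.3% and 64.1% in VC3201. The share of positive interactions of cco-1 RNAi with strain was 39.2% from the deposited values and 58.8% from the recovered reads, so its balance reversed among these genes. For the interactions of both RNAi the shares were 62.5% and 57.1% in N2, and 66.2% and 39.1% in VC3201.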

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

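The counts over other splits of the samples were planned, and the other tests in this part, those of explanations and the permuted residuals, were chosen after the results were seen. A group of results stood out because a response differed between groups by an interaction test. The response to cco-1 RNAi differed between N2 and VC3201 for 5819 genes. The response to elt-2 RNAi differed between the strains for 10603 genes, a comparison added after the data were seen. The effect of elt-2 RNAi differed with and without cco-1 RNAi for 1899 genes in N2 and for 5986 genes in VC3201.

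For comparisons of 3 against 3 libraries there are only 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave a count as large. The real count and the highest of the other splits were 4926 and 4 for cco-1 RNAi in N2, 6989 and 0 for elt-2 RNAi in N2, 4964 and 0 for elt-2 RNAi added to cco-1 RNAi in N2, and 7179 and 3 for VC3201 against N2. In VC3201 they were 9318 and 6 for cco-1 RNAi, 12494 and 0 for elt-2 RNAi, and 11807 and 0 for elt-2 RNAi added to cco-1 RNAi. For the interaction of both RNAi, 7 of 100 regroupings in N2 gave at least 1899 genes, with 4002 the highest other, and 14 of 100 in VC3201 gave at least 5986, with 11200 the highest other. These splits alone therefore did not exclude chance, but regrouping carries the effects of each RNAi into the interaction. With those effects kept, group means made additive and residuals permuted over the libraries, only the real data, 1 of 100 sets, reached the real count for each interaction, and the highest other count was 48 in N2 and 206 in VC3201 for both RNAi, 83 for cco-1 RNAi with strain and 14 for elt-2 RNAi with strain. Spread between these libraries without an interaction is thus argued against for all 4 counts. For the interaction of cco-1 RNAi with strain, 2 of 100 regroupings reached 5819 (highest other 6376), a share under 0.05. For that of elt-2 RNAi with strain, only the real grouping, 1 of 100, reached 10603 (highest other 9203). These regroupings also carry the effects of RNAi and strain, so they cannot decide whether an interaction arose by chance. Among genes raised by cco-1 RNAi, 3 of 100 regroupings reached the 556 lower with both RNAi (highest other 1868). For those lower in VC3201, 2 of 100 reached 603 (highest other 1758). Effects dealt at random among the raised genes gave means of 705 and 757.9. These simulations add spread to measured means, so their means are not directly comparable with 556 and 603. The effects also stayed within the raised genes, so the means cannot decide whether raised genes were lowered more often than other genes. Directly, 21.9% of the raised genes were lower with both RNAi, against 2401 of all 14561 tested genes. Both contrasts share the N2 libraries with cco-1 RNAi, so these shares do not settle that question either. In the splits for the counts of 556 and 603, regrouping likewise carries the effects of RNAi and strain into the count. The highest other splits can therefore be several times the real counts, and the shares do not decide on chance.

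elt-2 RNAi changed 5144 genes at least 2-fold in VC3201 and 1193 in N2. Unequal depth or quantile normalization as the whole cause is argued against by a ratio between strains of 3.4 among genes at 50 CPM or more with the normalization partly undone (640 and 188 of 3562 genes), and of 5.26 among genes with recovered reads (2140 and 407 of 5647), although the shape above the recovered range was not undone. The fall of elt-2 differed between strains by -0.06 (95% interval -0.66 to 0.55), but elt-2 was hardly lowered in VC3201 elt-2 RNAi replicate 3, and the difference was -0.38 (-0.91 to 0.14) without it and 0.2 (-0.37 to 0.78) without replicate 1, which leaves a stronger loss of elt-2 transcript in VC3201 open. The elt-2 response of 13 molting genes, a list added after the data were seen, was higher in VC3201 by a median of 2.34 (p = 0.00761 with an estimated correlation), in line with younger worms in the VC3201 elt-2 libraries, but these genes were also lower in VC3201 on control bacteria, by a median of -1.33. A candidate explanation is thus slower development of VC3201 on elt-2 RNAi, and a greater need for ELT-2 in the mutant stays open as well.

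All 17 intracellular pathogen response genes rose with elt-2 RNAi in both strains. With cco-1 RNAi their median change was 0.05 in N2, which argues against any RNAi food that targets a worm gene, for the list as a set. Single members did change there, with C17H1.7 at 1.13, skr-5 at 0.90, F22G12.1 at 0.65 and skr-4 at -0.71. The median was 0.055 in VC3201, where cuticle and oogenesis markers moved. Some members rose there too, with skr-3 at 1.36, C17H1.7 at 0.99, skr-4 at 0.92 and cul-6 at 0.82. The molting genes, however, rose less there with cco-1 RNAi (median 0.66) than with elt-2 RNAi (median 2.12). The median of 0.055 thus argues against younger worms for the list as a set and for a shift of the smaller size. It cannot decide on a larger shift or on the members that rose. The list's median lay above every library without elt-2 RNAi in 12 of 12 libraries with it, so an infection of the elt-2 RNAi cultures cannot be told apart from an effect of elt-2 RNAi, since no library separates them.

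cco-1 transcripts were lower with both RNAi than with cco-1 RNAi alone in either strain. Against control, elt-2 RNAi alone changed cco-1 by -0.31 in N2 (adjusted p = 0.00123) and by -0.37 in VC3201 (adjusted p = 6.53e-05). An effect of elt-2 RNAi on cco-1 by itself may thus be part of the cause. As the whole cause it is argued against by interactions of -0.49 in N2 (adjusted p = 0.00192) and -0.51 in VC3201 (adjusted p = 0.000446). A general fall of nuclear-encoded respiratory chain transcripts is argued against as the whole cause in N2, where 0 of 42 subunits fell by as much as cco-1 (the lowest change was -0.49, against -0.80 for cco-1), but it stays open in VC3201, where 8 of 42 did. A smaller shared fall, as part of the cause, cannot be decided by this comparison. Of 11 subunits encoded in mitochondrial DNA, 5 fell by as much as cco-1 in N2 and 0 in VC3201 (median -0.27 there, against -0.88 for cco-1), so a fall shared with these subunits stays open in N2 and is argued against as the whole cause in VC3201. The key sheet gives 50% cco-1 RNAi bacteria in the mix and on their own, but the amount eaten was not measured, and worms on the mix may have eaten more of these bacteria or responded more to cco-1 RNAi, which cannot be told apart here.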

How the results depend on the processing

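All alternatives in this part were planned except partly undoing the quantile normalization, which was added after the data were seen. Counts of changed genes, including genes raised by cco-1 RNAi and lower with both RNAi or in VC3201, stayed within 1.5 times the reported ones. This held for pseudocounts of 0.5 (91.3 to 100.4% of the reported count) and 5 (99 to 114.7%), no low-value filter (97.4 to 109.1%) and limma-voom (80.7 to 104.1%). It also held for fits of only the groups compared (82.9 to 108%). The normalization partly undone gave 81.7 to 116.7%, a range that also covers the counts of gene lists past the threshold. With replicate numbers as a replicate block the counts, again with those of lists, were 92.3 to 100.6% of those reported. Examples are 4930 genes for cco-1 RNAi in N2 and 12506 for elt-2 RNAi in VC3201. After group means were removed, libraries of the same number correlated with a mean r of 0.018 over 84 pairs (-0.104 to 0.15, with 7 pairs over 0.1), against a mean of -0.009 for other numbers, and 16 of 24 libraries correlated best with their own number. A weak link between equal numbers is therefore not excluded, and the replicate block gives the counts with it removed.

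A minimum change of 2-fold, by construction, left fewer genes: 346 for cco-1 RNAi, 1193 for elt-2 RNAi, 805 for elt-2 added to cco-1 RNAi and 292 for their interaction in N2, 549 between strains, 1200, 5144, 3852 and 997 for the same comparisons in VC3201, and 695 for cco-1 RNAi by strain. Genes raised by cco-1 RNAi and lower with both RNAi numbered 52 then, 23 of them with a negative interaction, and those lower in VC3201 62, with 49. With an estimated correlation fewer lists passed: 5 for cco-1 RNAi in N2, 11 for elt-2 RNAi in N2, 0 for the interaction in N2 (limma's camera), 4 between strains, 0 for cco-1 RNAi in VC3201, 6 for cco-1 RNAi by strain, and 2, 11 and 2 in VC3201 for elt-2 RNAi, for elt-2 added to cco-1 RNAi, and for their interaction. These estimates exceeded the preset for most lists, which widens the test by construction. A background of all genes, instead of the raised list, gave 6 lists in the ATFS-1-dependent genes. All 719 of these genes lie in the raised list, so by construction this background also counts enrichment of a list among raised genes.

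Leaving out each library in turn gave 4126 to 4503 genes for cco-1 RNAi in N2, 6273 to 6576 for elt-2 RNAi in N2, 4176 to 4504 for elt-2 added to cco-1 RNAi in N2, 1598 to 1853 for the interaction in N2 and 6304 to 6629 between strains. In VC3201 the ranges were 8604 to 9002, 12199 to 12309, 11391 to 11548 and 5404 to 5762, and for cco-1 RNAi by strain 5237 to 5854. Raised genes lower with both RNAi numbered 440 to 557, or 174 to 218 with a negative interaction, and those lower in VC3201 492 to 618, or 321 to 428. Of 1266 values for named genes under alternatives, 1254 kept direction and side of the threshold, 11 were no longer past it, 1 newly passed and none changed sign. The rise of atfs-1 with cco-1 RNAi in N2 did not pass without N2 control replicate 2 (adjusted p = 0.164) or 3 (0.082), or N2 cco-1 RNAi replicate 1 (0.12) or 3 (0.097). The strain difference of cco-1 did not pass without N2 control replicate 1 (0.11) or 2 (0.0926), N2 cco-1 RNAi replicate 2 (0.0917), VC3201 control replicate 1 (0.0736) or 2 (0.064), or VC3201 cco-1 RNAi replicate 1 (0.128). Planned fits with DESeq2 size factors, with library sizes only, with the DESeq2 test and with a filter on counts were not run, because the values are not counts. With 8 to 38 reads at 1 CPM, genes near that level carry large counting error.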

Other observations

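Other gene groups also moved. VC3201 had higher levels than N2 on control bacteria for 55 of 79 cytosolic ribosome genes (median 0.24, adjusted p = 5.24e-08, but adjusted p = 0.222 with an estimated correlation), and lower levels for 12 of 14 body wall muscle markers (median -0.33, adjusted p = 0.000109, and 0.189 with an estimated correlation). With cco-1 RNAi in N2, 11 of 19 glycolysis genes rose and 2 fell (median 0.17, adjusted p = 0.000178), among them the aldolase gene aldo-1 (WBGene00011474), from 143 ± 1.03 to 345 ± 7.84 CPM (1.27). With elt-2 RNAi in N2, 15 of the same genes fell and 3 rose (median -0.24, adjusted p = 0.00156). Of 23 innate immune effectors 13 fell with elt-2 RNAi in N2 and 8 rose (median -0.33, adjusted p = 0.00049), with the lysozyme gene lys-1 (WBGene00003090) going from 293 ± 12.4 to 50.8 ± 2.70 CPM (-2.51). Neuron markers rose in 9 of 15 cases there and none fell (median 0.36, adjusted p = 0.000467). The glycolysis, immune and neuron lists held with an estimated correlation (adjusted p = 0.0287, 0.033, 0.012 and 0.033 in the order given).

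Fatty acid synthesis and desaturation genes fell in 10 of 14 cases when elt-2 RNAi was added to cco-1 RNAi in N2 and rose in 1 (median -0.46, adjusted p = 1.54e-05). fat-7 fell there from 4.26 ± 0.580 to 0.347 ± 0.0970 CPM (-1.96). Glutathione S-transferases fell in 18 of 33 cases (median -0.31, adjusted p = 0.000112), and innate immune effectors in 12 of 23 (median -0.66, adjusted p = 1.15e-05), and all of these held with an estimated correlation. Of 31 major sperm protein genes, a list added after the data were seen, 28 rose with cco-1 RNAi in N2, 29 with elt-2 RNAi in N2 and 31 with elt-2 RNAi in VC3201 (p = 0.0175, 0.0807 and 0.0438 with an estimated correlation, not adjusted over lists). On control bacteria 28 of them were higher in VC3201 than in N2 and 0 lower (p = 0.0153 with an estimated correlation, likewise not adjusted). Of 120 cuticle collagen genes, also added, 6 were higher and 96 lower in VC3201 than in N2 on control bacteria, and 90 rose and 9 fell with cco-1 RNAi in VC3201. With elt-2 RNAi 4 rose and 76 fell in N2, whereas 84 rose and 23 fell in VC3201.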
